A study of Mus musculus with 12 samples.

How the data were processed

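Polyadenylated RNA was sequenced from 12 libraries of immortalized mouse mesenchymal stem cells, 3 libraries in each of 4 groups. Per the labels' protocols, RNA was purified on columns, treated with DNase and made into libraries with standard Illumina steps. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with 21881 genes and 12 columns, each of which carried the name of 1 library. Per the submitters' processing notes, TopHat 1.2.0, Cufflinks 1.0.3 and the mouse genome build mm9 were used, with no setting given in the sources used here. FPKM is a share of a library's fragments divided by transcript length, so a large change in a few abundant genes moves every other value, and the table gives no read counts. Whether counting used the strand is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart.

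The number of reads per library is not known. The relative depth was read from genes with FPKM under 0.3 in both of 2 libraries: where each library holds 1 read of a gene, the ratio of the values is the inverse ratio of the depths, and that ratio was the most common one. Set to 1 for KO_siCtrl replicate 0, the shallowest library, the relative depth was 1.11 to 1.82 in the others. The ratio found for each pair of libraries differed from the ratio of these depths by at most 0.00085%. Simulated libraries of known depth gave back their depths.

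Groups were taken from the sample titles, which also number the libraries of each group 0, 1 and 2. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries with the same number deviated from their group means together: the correlation across genes of these deviations was 0.127 to 0.465 in the 12 same-number pairs of compared groups, all above the limit of 0.1, and 10 of the 12 libraries correlated best with their own number. Between groups not compared the lowest was 0.092. The numbers were therefore taken to pair the libraries, from the data and not from a label. The reported fit and its tests do not use this pairing, and a fit with the replicate number as a fixed block was run beside them.

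Genes with FPKM of at least 1 in at least 3 libraries were tested, which left 11801. Values were analysed as log2(FPKM + 1) with limma 3.58.1 (R 4.3.3): a linear model over all 12 libraries with 1 coefficient per group and 8 residual degrees of freedom, a moderated two-sided test with a trend of the variance on the mean, and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at an adjusted p under 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Gene names were unique, so the planned choice between summing and selecting entries of 1 name did not arise.

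The comparisons were KO_siCtrl against WT_siCtrl, KO_let-7g and KO_siNr6a1 each against KO_siCtrl, and KO_let-7g against KO_siNr6a1, the last being the test of the difference between the treatments. Nr6a1 and Dicer1 were also compared with a two-sided exact permutation test of 3 against 3 libraries, which cannot give a p below 0.1. The groups, comparisons, tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

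Each of 26 gene lists was described by the number of members called over all genes and by the number called when p-values were adjusted over the list alone. The lists covered let-7 targets, imprinted and fetal growth genes, pluripotency and germline genes, Hox genes, microRNA processing, mitosis, DNA replication, p53 targets, interferon-induced genes, inflammation, extracellular matrix, TGF-beta or YAP response, ERK response, cholesterol, endoplasmic reticulum and amino acid stress, glycolysis and hypoxia, ribosomal proteins and replication-dependent histones. Markers of mesenchymal stem cells, osteoblasts and cartilage, adipocytes, muscle, blood, endothelium, epithelium and neural cells completed them. The 22 lists with at least 5 tested members were tested against all other genes with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated from the data called 0 lists in each of the 4 comparisons (4, 1, 1 and 3 lists at an unadjusted p under 0.05), and fry, which asks whether the members of a list move one way without comparing them with other genes, called 15, 10, 3 and 11. Every list call below therefore rests on the preset correlation.

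Named genes were Nr6a1 and Dicer1, the 10 largest rises and 10 largest falls of a comparison (5 each in KO_let-7g against KO_siNr6a1), and up to 4 members per list with the smallest adjusted p. To these were added the 5 genes each way that moved most in both treatments or moved back most. The largest changes had to be called, to have groups that did not overlap and to have a mean FPKM of at least 5 in the higher group, and predicted gene models were left out. Some genes taken by this rule are small nucleolar RNAs, microRNA hairpins and Rpph1, which are shorter than a sequencing fragment or lack a poly(A) tail. The FPKM values of these small RNAs are not reliable in these libraries, and they are counted but not described: 4 of the largest rises and 2 of the largest falls in KO_siCtrl against WT_siCtrl, 4 and 1 in KO_let-7g and 4 and 2 in KO_siNr6a1 against KO_siCtrl, and 1 and 2 in KO_let-7g against KO_siNr6a1. Some other genes taken by the rule are not reported here. Replication-dependent histone genes and ribosomal protein genes have near-identical copies or processed pseudogenes whose reads can be split in error, so their values are uncertain.

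Sequences of 3′ untranslated regions (3′ UTRs) came from GENCODE M21 (GRCm38), which is not the build the authors used, so no genome coordinates are given. Of the genes in the table, 19609 were matched by symbol to a transcript with a 3′ UTR of at least 20 bases, and 1728 of the matches used an older symbol. The longest transcript with a 3′ UTR was used. Sites for let-7 were the 8mer CTACCTCA, the 7mer-m8 CTACCTC and the 6mer TACCTC. The median log2 fold change of genes with an 8mer was compared with that of genes without a 6mer, camera was run on the same sets, and the same was done for 14 other microRNA seeds. As a check for UTR length and base composition, 10000 sets of genes without a site, matched on 3′ UTR length and GC content, were drawn. In a scan added after the data were examined, the presence of each of 16135 7-base words in the 3′ UTRs of 11110 genes was related to log2 fold change after length and GC content had been removed. The z of a word was compared with the 95th percentile of the largest z in 100 permutations of the genes.

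Comparisons that share the KO_siCtrl libraries share their chance values. For each pair of comparisons, unchanged groups were simulated 100 times against the same controls by shuffling residuals within each replicate number, a scheme adopted after free shuffling across numbers had given a draw with many calls. The tests were run on simulated data in which, of 11801 genes, 100 were changed by each of 2 sizes. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2, and the noise was independent between libraries. The shares recovered therefore do not cover genes with lower values or the joint deviations of same-number libraries. At a log2 change of 1, 97% were recovered for KO_siCtrl against WT_siCtrl, 93% for KO_let-7g and 93% for KO_siNr6a1 against KO_siCtrl, and 95% for KO_let-7g against KO_siNr6a1. At a log2 change of 0.5, the shares were 44%, 42%, 42% and 49%.

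Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, scaling by the upper quartile, by quantiles or by median of ratios, variance moderation without trend or with robust settings, fits of 2 groups only, the replicate block, library weights, stricter thresholds, other definitions of let-7 sites, and each library left out in turn. Added after the data were examined were fits without genes holding AGCCTT in the 3′ UTR, without small RNA and predicted genes, and without replicate 0 of every group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 handled sequences and resampling, statmod 1.5.0 was loaded with limma, and matplotlib 3.10.9 drew the plots.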

Results

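RNA was sequenced from immortalized mouse mesenchymal stem cells of bone marrow, fibroblast-like cells grown as lines from single cells. One genotype (WT) carried intact, floxed Dicer1 alleles, and the other (KO) had lost Dicer1, the gene of the nuclease that cuts microRNA precursors into mature microRNAs. WT and KO cells received a control siRNA (WT_siCtrl, KO_siCtrl), and KO cells also received a let-7g duplex (KO_let-7g) or an siRNA against Nr6a1 (KO_siNr6a1), each at 20 nM for 48 h. Each of the 4 groups had 3 libraries. In each library 15469 to 16602 genes had an FPKM above 0 and 11032 to 11465 had an FPKM of at least 1. Total reads are not known, but relative depth was 1 to 1.31 in the KO_siCtrl libraries, 1.11 to 1.29 in WT_siCtrl, 1.13 to 1.56 in KO_siNr6a1 and 1.34 to 1.82 in KO_let-7g, so each KO_let-7g library was deeper than each KO_siCtrl library. Levels below are mean FPKM ± SD over the 3 libraries of a group, and fold changes are on the log2(FPKM + 1) scale. Medians of lists are of log2 fold changes. The labels do not say how many clonal lines were used, so genotype and line cannot be separated, and p-values measure only the spread between these libraries, which may be technical.

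Nr6a1, an orphan nuclear receptor of embryonic and germ cells, was the gene targeted by 1 of the siRNAs. Its level was 1.12 ± 0.158 in WT_siCtrl, 11.7 ± 1.32 in KO_siCtrl, 4.22 ± 1.04 in KO_let-7g and 3.68 ± 0.539 in KO_siNr6a1. It rose in KO_siCtrl against WT_siCtrl (log2 fold change 2.58, adjusted p = 1.28e-07) and fell against KO_siCtrl in KO_let-7g (-1.3, adjusted p = 4.67e-05) and in KO_siNr6a1 (-1.44, adjusted p = 7.34e-05). The difference between the treatments was 0.14 (adjusted p = 0.466) and did not pass the test, and its sign turned under quantile scaling (-0.03) and without KO_let-7g replicate 1 (-0.01). The longest annotated Nr6a1 transcript with a 3′ UTR has a 3′ UTR of 4457 bases with 3 let-7 8mer sites, CTACCTCA, starting at bases 371, 1228 and 4135 of the UTR, and 8 sites of the 7mer CTACCTC in all. Dicer1 was measured over the whole gene, so a deletion of part of it need not bring the value to 0. Dicer1 stood at 6.58 ± 1.45 in WT_siCtrl, 3.86 ± 0.214 in KO_siCtrl, 2.7 ± 0.29 in KO_let-7g and 3.15 ± 0.392 in KO_siNr6a1, and fell in KO_siCtrl against WT_siCtrl (-0.62, adjusted p = 0.00208). Dicer1 was also called lower in KO_let-7g against KO_siCtrl (-0.4, adjusted p = 0.0306), a call lost in 5 of 25 settings (highest adjusted p = 0.105). It was not called in KO_siNr6a1 against KO_siCtrl (-0.23, adjusted p = 0.214), but was with library weights (adjusted p = 0.0325). The exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest it allows, for both genes in each comparison with KO_siCtrl, and 0.6 for Nr6a1 and 0.3 for Dicer1 between KO_let-7g and KO_siNr6a1.

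**Figure D1:**
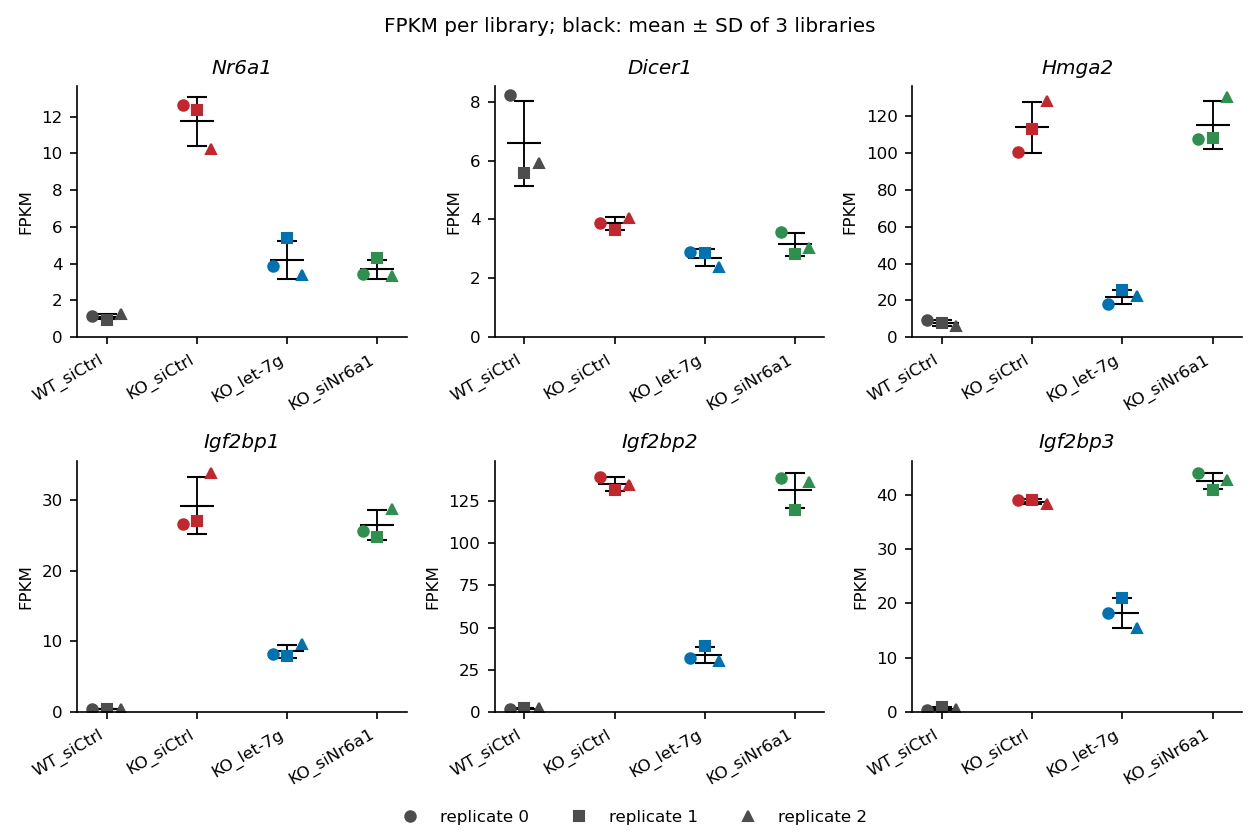
FPKM of Nr6a1, Dicer1, Hmga2 and Igf2bp1 to Igf2bp3 in each of the 12 libraries (points), with the mean and SD of each group. Nr6a1 was highest in KO_siCtrl (mean 11.7) and lower in KO_let-7g (4.22) and KO_siNr6a1 (3.68), while Hmga2 was at 22 ± 3.81 in KO_let-7g and 115 ± 13 in KO_siNr6a1.

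The comparison of KO_siCtrl with WT_siCtrl asks what differs in cells without Dicer1. Among the largest rises, Igf2bp2 stood at 135 ± 3.9 against 1.92 ± 0.286 FPKM (log2 fold change 5.55), Igf2bp3 at 38.8 ± 0.449 against 0.589 ± 0.251 (4.66) and Igf2bp1 at 29.2 ± 4.06 against 0.412 ± 0.0387 (4.41). All 3 encode RNA-binding proteins. Hmga2, a chromatin protein of embryonic growth, rose from 7.58 ± 1.46 to 114 ± 13.7 (3.75). Mgat3, a glycosyltransferase, rose to 33.8 ± 3.26 from 0.48 ± 0.0476 (4.55), the mitochondrial arginase Arg2 to 64 ± 9.07 from 2.2 ± 0.618 (4.35), and the lipopolysaccharide-binding protein Lbp to 23.8 ± 5.39 from 0.228 ± 0.114 (4.32). Adjusted p was at most 9.49e-07 for these genes.

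Genes of contraction and matrix were among the largest falls in KO_siCtrl. The smooth-muscle genes Acta2 (17.1 ± 2.27 against 1282 ± 144 FPKM, -6.15), Tagln (1.55 ± 0.391 against 152 ± 39, -5.88) and Actg2 (0.322 ± 0.184 against 69.99 ± 14.2, -5.74) fell together with the matrix genes Postn (2.25 ± 1.39 against 221 ± 43.5, -6.16) and Tnc (4.64 ± 0.173 against 305 ± 72.2, -5.74). Fabp4, a fatty-acid-binding protein of adipocytes, stood at 1.93 ± 1.67 against 302 ± 49.9 (-6.87), Dpysl3 at 0.116 ± 0.0458 against 88.4 ± 8.59 (-6.32) and Il1rn, the antagonist of the interleukin-1 receptor, at 0.136 ± 0.081 against 68.5 ± 43.3 (-5.73). Adjusted p was at most 5.09e-07 for these genes. Of 11801 genes tested with limma, 6413 passed an adjusted p of 0.05, 3439 higher and 2974 lower in KO_siCtrl, and 1459 of them changed by at least 1 log2 unit (640 higher and 819 lower). Which direction held more genes also depended on scaling, with 2918 higher and 3366 lower by the upper quartile and 3043 and 3289 by median of ratios.

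Among the gene lists, let-7 targets as a group were higher in KO_siCtrl: 28 of 38 tested members rose and 1 fell (29 and 1 adjusted over the list alone). The member that fell was Dicer1, the deleted gene, which is on this list and had no let-7 8mer or 7mer-m8 in the 3′ UTR used. Camera called the list (median 0.92, adjusted p = 3.11e-09, and adjusted p = 0.11 with an estimated correlation). Of the inflammation genes, 17 of 22 tested members rose and 2 fell (18 and 2 adjusted over the list alone). They included the chemokines Ccl2 (178 ± 16.5 against 53 ± 3.98 FPKM, 1.73) and Cxcl5 (127 ± 26.5 against 14 ± 3.45, 3.1) and the cytokines Lif (9.34 ± 2.34 against 1.04 ± 0.143, 2.32) and Il33 (17.6 ± 3.52 against 0.532 ± 0.0188, 3.58). Camera called this list as well (median 1.36, adjusted p = 4.97e-05, and adjusted p = 0.102 with an estimated correlation). Of the genes induced by ERK signalling, 13 of 24 tested members rose and 0 fell (the same counts adjusted over the list alone). Among them were the growth factor Ereg (12 ± 1.16 against 0.862 ± 0.15, 2.8) and the phosphatase Dusp6 (25.2 ± 3.19 against 5.36 ± 0.85, 2.05). Camera called the ERK list (median 0.71, adjusted p = 0.000304, and adjusted p = 0.13 with an estimated correlation). Of the replication-dependent histone genes, whose mRNAs lack a poly(A) tail and have near-identical copies, 21 of 30 tested members rose and 0 fell (the same counts adjusted over the list alone). Camera called the list higher (median 0.84, adjusted p = 0.00033, and adjusted p = 0.622 with an estimated correlation), and the call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.0767).

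The lists lower in KO_siCtrl held matrix, muscle, bone and ribosomal genes. Of the extracellular matrix genes, 7 of 41 tested members rose and 26 fell (the same counts adjusted over the list alone). They included the collagen Col1a2 (283 ± 12.9 against 1378 ± 109 FPKM, -2.28) and the matrix protease Mmp2 (2.87 ± 0.28 against 24.8 ± 3.45, -2.73). Camera called the matrix list (median -0.98, adjusted p = 7.7e-05, and adjusted p = 0.34 with an estimated correlation). Of the muscle genes, 2 of 15 tested members rose and 10 fell (the same counts adjusted over the list alone). Calponin 1, Cnn1, stood at 0.183 ± 0.111 against 49.95 ± 4.61 (-5.43) and the myosin light chain Myl9 at 8.71 ± 1.15 against 299 ± 30.3 (-4.95). Camera called the muscle list (median -1.81, adjusted p = 0.000157, and adjusted p = 0.0557 with an estimated correlation). Of the osteoblast and cartilage genes, 5 of 17 tested members rose and 10 fell (the same counts adjusted over the list alone). The osteoblast transcription factor Sp7 stood at 0.412 ± 0.157 against 38.6 ± 16 (-4.73) and the osteocalcin gene Bglap at 0.474 ± 0.497 against 41.3 ± 20.1 (-4.75). Camera called the osteoblast and cartilage list (median -1.33, adjusted p = 0.0133, and adjusted p = 0.622 with an estimated correlation). Of the ribosomal protein genes, 1 of 41 tested members rose and 18 fell (the same counts adjusted over the list alone). Camera called them lower (median -0.21, adjusted p = 0.00697, and adjusted p = 0.688 with an estimated correlation), and under quantile scaling the median was -0.02 and the call was lost (adjusted p = 0.573).

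The other 14 lists tested were not called in KO_siCtrl against WT_siCtrl. Members that rose and fell, with the same counts adjusted over the list alone, were 12 and 3 of 23, adjusted p = 0.0906 for glycolysis and hypoxia, 2 and 7 of 14, adjusted p = 0.0656 for adipocyte genes, 10 and 3 of 23, adjusted p = 0.277 for stress genes, 4 and 7 of 21, adjusted p = 0.277 for p53 targets and 5 and 9 of 18, adjusted p = 0.277 for mesenchymal stem cell markers. They were 5 and 8 of 20, adjusted p = 0.244 for TGF-beta or YAP response, 3 and 6 of 24, adjusted p = 0.244 for cholesterol genes, 8 and 5 of 19, adjusted p = 0.588 for microRNA processing and 1 and 0 of 6, adjusted p = 0.606 for neural genes. For Hox genes they were 8 and 4 of 20, adjusted p = 0.949, with Hoxc13 at 0.688 ± 0.158 against 13.7 ± 3.07 FPKM (-3.1), for fetal growth genes 5 and 4 of 13, adjusted p = 0.949, for interferon-induced genes 9 and 8 of 35, adjusted p = 0.949, for mitosis genes 6 and 4 of 28, adjusted p = 0.949, and for DNA replication genes 6 and 5 of 32, adjusted p = 0.949. The Hox and fetal growth lists had a positive median (0.16 and 0.03), a negative mean (-0.18 and -0.05) and an upward camera direction. Too few members passed the filter to test the other 4 lists: 2 pluripotency and germline genes (1 rose and 1 fell), 3 blood genes (2 rose, highest Cd74 with a mean FPKM of 28.6), 3 endothelial genes (highest Eng, 41.9) and 1 epithelial gene (Krt19, 0.809). Calls in this comparison were lost in 2 of 27 settings for Eng (highest adjusted p = 0.0562) and in 7 of 26 for Krt19 (0.132).

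**Figure D2:**
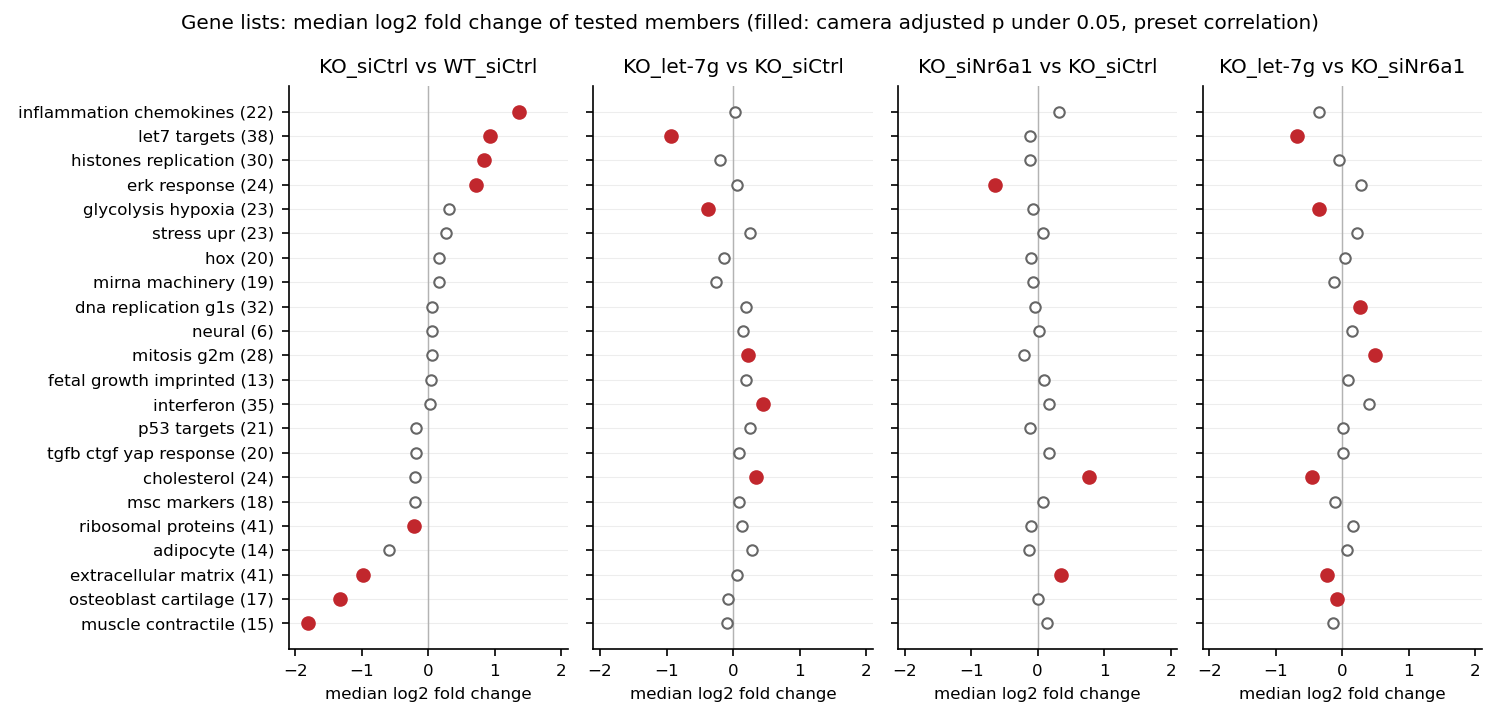
Median log2 fold change of the tested members of each of the 22 gene lists (vertical axis) in the 4 comparisons, with filled red points where camera at the preset correlation gave an adjusted p under 0.05. The let-7 targets had medians of 0.92 in KO_siCtrl against WT_siCtrl, -0.94 in KO_let-7g against KO_siCtrl and -0.12 in KO_siNr6a1 against KO_siCtrl.

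The comparison of KO_let-7g with KO_siCtrl asks what differs when a let-7g duplex takes the place of the control siRNA in cells without Dicer1. Genes that rose most included the transmembrane glycoprotein Gpnmb (29.4 ± 7.26 against 2.1 ± 0.217 FPKM, log2 fold change 3.27), the secreted carbonic anhydrase Car6 (9.29 ± 2.16 against 0.0833 ± 0.0416, 3.23), the matrix protease Mmp3 (10.9 ± 1.45 against 0.285 ± 0.179, 3.21) and the glycogen-binding protein Stbd1 (18.7 ± 1.26 against 1.5 ± 0.233, 2.98). Cox6a2, a subunit of cytochrome c oxidase in muscle, rose to 5.09 ± 1.47 from 0.0911 ± 0.101 (2.45), and Prkcdbp, a protein of caveolae, to 41.6 ± 3.3 from 7.49 ± 1.77 (2.35). The falls were led by haptoglobin, Hp (8.3 ± 4.6 against 59 ± 1.58, -2.81), Tmem119 (8.6 ± 0.953 against 50.7 ± 3.65, -2.43), Arg2 (11.2 ± 1.46 against 64 ± 9.07, -2.4), the DNA-binding protein Arid3a (1.86 ± 0.408 against 13.8 ± 1.06, -2.38) and Hmga2 (22 ± 3.81 against 114 ± 13.7, -2.33). Kbtbd11 fell to 1.48 ± 0.446 from 11.5 ± 0.86 (-2.35). Adjusted p was at most 0.00036 for these genes. In all, 5383 of 11801 genes passed the test, 3241 higher and 2142 lower in KO_let-7g. These libraries were 1.34 to 1.82 times as deep as the shallowest KO_siCtrl library. Of the called genes 60.2% were higher, against 49.9% under quantile scaling (2600 higher and 2615 lower).

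Of the let-7 targets, 0 of 38 tested members rose and 30 fell (the same counts adjusted over the list alone). The transcriptional repressor Hic2 stood at 1.87 ± 0.24 against 10.0 ± 0.497 FPKM (-1.94) and Igf2bp2 at 33.7 ± 4.64 against 135 ± 3.9 (-1.98). Camera called the let-7 target list (median -0.94, adjusted p = 8.18e-15, and adjusted p = 0.0974 with an estimated correlation). Of the glycolysis and hypoxia genes, 4 of 23 tested members rose and 10 fell (4 and 11 adjusted over the list alone). The glycolytic enzyme Pgam1 stood at 398 ± 18.4 against 792 ± 57 (-0.99) and the lactate transporter Slc16a3 at 8.1 ± 1.48 against 20.3 ± 1.03 (-1.24), while Ndrg1, a hypoxia-induced gene, rose (1.94). Camera called this list lower (median -0.37, adjusted p = 0.0155, and adjusted p = 0.824 with an estimated correlation). Of the cholesterol genes, 12 of 24 tested members rose and 0 fell (12 and 1 adjusted over the list alone). Among them were Insig1, a sterol sensor, at 108 ± 5.02 against 46 ± 4.39 (1.22) and the synthesis enzyme Fdft1 at 39.7 ± 2.33 against 24.5 ± 0.897 (0.68). Camera called the cholesterol list (median 0.35, adjusted p = 0.0155, and adjusted p = 0.824 with an estimated correlation). Without genes holding AGCCTT in the 3′ UTR, a word described below that 13 of 24 members carried, the cholesterol call was lost (median 0.26, adjusted p = 0.136). The glycolysis and hypoxia call was lost too (adjusted p = 0.0736), although only 2 of 23 members carried the word and the median stayed at -0.37.

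Of the interferon-induced genes, 16 of 35 tested members rose and 1 fell (the same counts adjusted over the list alone). Ifi204 stood at 43 ± 4.1 against 26.9 ± 2.94 FPKM (0.66) and the antigen transporter Tap1 at 24.8 ± 3.06 against 9.56 ± 1.04 (1.29). Camera called the interferon list (median 0.45, adjusted p = 0.0234, and adjusted p = 0.824 with an estimated correlation). The call was lost without KO_siCtrl replicate 2 (adjusted p = 0.0581) or KO_let-7g replicate 1 (0.0592). Of the mitosis genes, 12 of 28 tested members rose and 3 fell (the same counts adjusted over the list alone). They included the transcription factor Foxm1 (77.6 ± 5.47 against 25.8 ± 1.18, 1.55) and the kinase Aurkb (93 ± 6.2 against 50.7 ± 5.16, 0.86). Camera called the mitosis list narrowly (median 0.23, adjusted p = 0.0467, and adjusted p = 0.824 with an estimated correlation). That call was lost without WT_siCtrl replicate 1 (adjusted p = 0.051), KO_siCtrl replicate 1 (0.0711), KO_siCtrl replicate 2 (0.0719) or KO_let-7g replicate 0 (0.0631), under upper quartile (0.0505) and median of ratios (0.0704) scaling, without trend (0.0606), with library weights (0.0622) and without AGCCTT genes (0.136). The other 17 lists were not called, with DNA replication (14 and 3 of 32, adjusted p = 0.0521) and microRNA processing (3 and 9 of 19, adjusted p = 0.0798) nearest. With the replicate block both were called (adjusted p = 0.0351, higher, and 0.0422, lower). Median, mean and camera direction differed in sign for the uncalled fetal growth, inflammation, matrix, ERK and stem cell lists.

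Genes with let-7 sites were lower in KO_let-7g as a set. The 438 genes with an 8mer in the 3′ UTR had a median log2 fold change of -0.24 against 0.12 in the 8185 genes with no 6mer, a difference of -0.37 (camera p = 3.34e-12, adjusted p = 5.01e-11 over 15 microRNA seeds, and adjusted p = 0.0065 with an estimated correlation). Of the 8mer genes 187 fell and 67 rose, so that 42.7% fell against 14.3% of the genes without a 6mer. The size of the difference depended on the filter: with no filter, over 642 genes with an 8mer, it was -0.03 in this comparison and -0.06 between KO_let-7g and KO_siNr6a1, and both kept their camera call. In 10000 sets of genes matched on 3′ UTR length and GC content the median was 0.13, and 0 sets were as low as the 8mer genes. The 1199 genes with a 7mer-m8 had a median of -0.19. In KO_siCtrl against WT_siCtrl the 8mer difference was 0.15, which failed adjustment over the seeds tested (adjusted p = 0.371 by camera). Its unadjusted p was 0.0266 at the preset correlation, 0.105 with an estimated correlation and 0.056 without WT_siCtrl replicate 2. Of the matched sets 0 were as high, and 40.9% of the 8mer genes rose against 28% of the others. In KO_siNr6a1 against KO_siCtrl it was 0.03 (adjusted p = 0.799), and between KO_let-7g and KO_siNr6a1 it was -0.35 (adjusted p = 1.4e-18, and 0.00103 with an estimated correlation). None of the 14 other seeds had an adjusted p under 0.05 in any of the 4 comparisons.

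**Figure D3:**
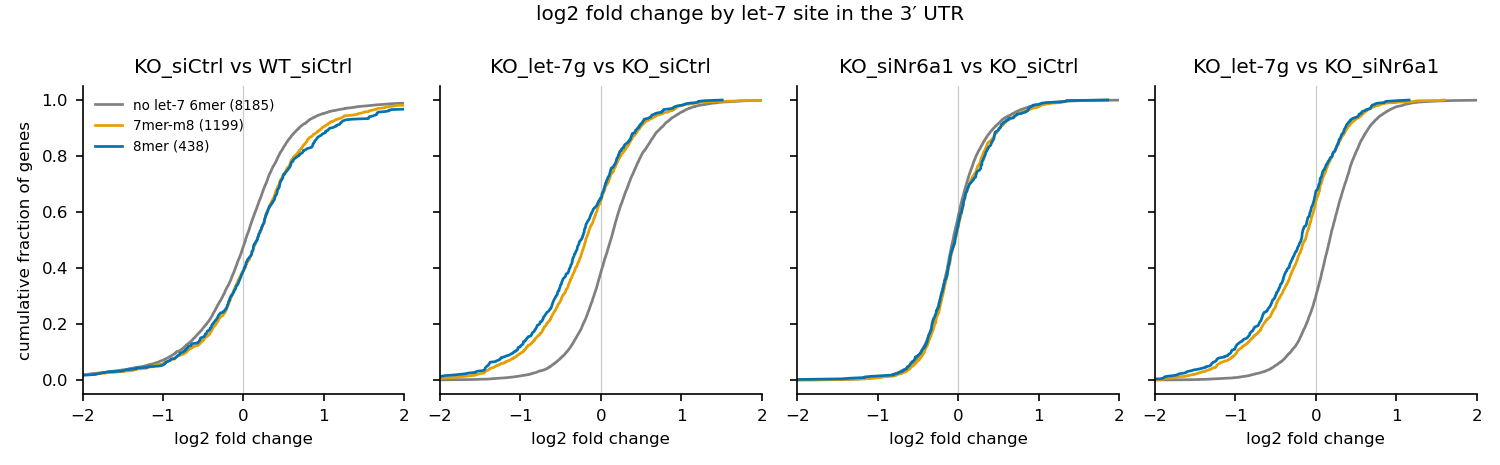
Cumulative fraction of genes (vertical axis) by log2 fold change (horizontal axis) in each comparison, for 8185 genes with no let-7 6mer in the 3′ UTR, 1199 with a 7mer-m8 and 438 with an 8mer. The 8mer genes lie to the left in KO_let-7g against KO_siCtrl (median -0.24 against 0.12) and against KO_siNr6a1 (-0.18 against 0.17).

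The comparison of KO_siNr6a1 with KO_siCtrl asks what differs when the siRNA against Nr6a1 takes the place of the control siRNA in cells without Dicer1. The largest rises included the collagen-binding proteoglycan Fmod (27.3 ± 6.92 against 1.51 ± 0.747 FPKM, log2 fold change 3.51), the opioid precursor Penk (38.1 ± 16.4 against 6.08 ± 2.44, 2.46), the Wnt modulator Sfrp2 (157 ± 56.4 against 33.7 ± 14.8, 2.21), the hyaluronan synthase Has2 (10.6 ± 1.08 against 1.53 ± 0.493, 2.21) and the Wnt ligand Wnt4 (12.5 ± 5.1 against 2.08 ± 1.04, 2.09). The ephrin receptor Ephb6 rose to 19.06 ± 4.84 from 2.86 ± 0.782 (2.37). The falls were led by the integrin Itgb7 (9.25 ± 1.02 against 55.5 ± 12.1, -2.44), the semaphorin Sema7a (7.13 ± 0.0745 against 41.6 ± 11.1, -2.36) and Arg2 (14 ± 2.26 against 64 ± 9.07, -2.12). The RNA-binding proteins Celf4 (5.05 ± 0.313 against 21.8 ± 2.41, -1.91) and Ptbp2 (15.3 ± 0.554 against 58.2 ± 7.81, -1.85) and the cyclin-dependent kinase inhibitor Cdkn2d (8.84 ± 2.1 against 31.7 ± 0.507, -1.75) also fell. Adjusted p was at most 0.0021 for these genes. In all, 3474 of 11801 genes passed the test, 1556 higher and 1918 lower. The balance turned under median of ratios scaling (1799 higher and 1511 lower) and among genes that changed by at least 1 log2 unit (192 and 118). Of the genes called higher 69.2% held AGCCTT, a 3′ UTR word described below, against 32.4% of those lower and 41.4% of those not called. In KO_let-7g against KO_siCtrl the shares were 54.3% of those higher and 39.6% of those lower. The count was 5248 with the replicate block, 5528 with library weights and 2021 without replicate 0 of every group.

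Cholesterol genes rose together in KO_siNr6a1: 20 of 24 tested members rose and 1 fell (21 and 1 adjusted over the list alone). Insig1 stood at 125 ± 9.21 against 46 ± 4.39 FPKM (1.42) and the synthesis enzymes Fdft1 at 55.4 ± 5.82 against 24.5 ± 0.897 (1.14) and Sc4mol at 209.9 ± 27.4 against 58.1 ± 4.09 (1.83). Camera called the cholesterol list (median 0.77, adjusted p = 7.78e-14, and adjusted p = 0.322 with an estimated correlation). Of the extracellular matrix genes, 17 of 41 tested members rose and 3 fell (21 and 4 adjusted over the list alone). Among them were the protease inhibitor Timp1 (136 ± 19.6 against 68.6 ± 13, 0.98) and the laminin Lamc1 (86.5 ± 10.5 against 40.9 ± 6.31, 1.07). Camera called the matrix list (median 0.36, adjusted p = 4.07e-05, and adjusted p = 0.573 with an estimated correlation). Of the genes induced by ERK signalling, 1 of 24 tested members rose and 13 fell (1 and 14 adjusted over the list alone). Dusp6 stood at 14 ± 1.2 against 25.2 ± 3.19 (-0.81) and the transcription factor Etv4 at 17.3 ± 3.16 against 43 ± 13.2 (-1.24). Camera called the ERK list lower (median -0.65, adjusted p = 0.0288, and adjusted p = 0.573 with an estimated correlation). This call was lost with the replicate block (adjusted p = 0.0944), with library weights (0.0599), at a mean FPKM of at least 5 (0.185) and without KO_siCtrl replicate 1 (0.0553), KO_siCtrl replicate 2 (0.0623) or KO_siNr6a1 replicate 0 (0.0702). The let-7 targets, with Nr6a1 itself among the members that fell, were not called (7 and 9 of 38, adjusted p = 0.916), nor were the other 18 lists. Median, mean and camera direction differed in sign for the uncalled DNA replication, p53, glycolysis, ribosomal, stem cell, adipocyte and neural lists.

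KO_let-7g and KO_siNr6a1 were then compared directly, which tests the difference between the treatments. Mmp3 (10.9 ± 1.45 against 0.324 ± 0.186 FPKM, log2 fold change 3.17), Car6 (9.29 ± 2.16 against 0.544 ± 0.448, 2.76), Gpnmb (29.4 ± 7.26 against 3.88 ± 0.29, 2.62) and Cox6a2 (5.09 ± 1.47 against 0.18 ± 0.0819, 2.34) were higher in KO_let-7g. Fmod (2.27 ± 1.13 against 27.3 ± 6.92, -3.15) and Penk (5.69 ± 3.49 against 38.1 ± 16.4, -2.63) were lower. Adjusted p was at most 0.000898 for these genes. Of the mitosis genes, 21 of 28 tested members rose and 0 fell (22 and 1 adjusted over the list alone). Foxm1 stood at 77.6 ± 5.47 against 38.4 ± 1.22 (0.99). Camera called the mitosis list higher (median 0.49, adjusted p = 8.19e-05, and adjusted p = 0.248 with an estimated correlation). Of the let-7 targets, 1 of 38 tested members rose and 26 fell (the same counts adjusted over the list alone). The repressor E2f6 stood at 7.84 ± 0.172 against 21.8 ± 1.68 (-1.37). Its level in KO_siCtrl was 11.3 ± 0.0914, so part of this difference was a rise in KO_siNr6a1. Camera called the let-7 target list (median -0.68, adjusted p = 1.04e-17, and adjusted p = 0.0583 with an estimated correlation). Of the cholesterol genes, 1 of 24 tested members rose and 13 fell (1 and 14 adjusted over the list alone). Camera called the cholesterol list lower (median -0.45, adjusted p = 8.85e-07, and adjusted p = 0.248 with an estimated correlation). Of the matrix genes, 4 of 41 tested members rose and 17 fell (5 and 17 adjusted over the list alone). Thrombospondin 1 (Thbs1) stood at 155 ± 26.3 against 619.6 ± 67.4 (-2.005). Camera called the matrix list (median -0.22, adjusted p = 0.000245, and adjusted p = 0.3 with an estimated correlation). Of the glycolysis and hypoxia genes, 2 of 23 tested members rose and 11 fell (the same counts adjusted over the list alone). Slc16a3 stood at 8.1 ± 1.48 against 31.4 ± 6.38 (-1.83). Camera called the glycolysis list (median -0.34, adjusted p = 0.000262, and adjusted p = 0.248 with an estimated correlation).

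The direct comparison also gave calls for DNA replication and for osteoblast and cartilage genes. Of the DNA replication genes, 15 of 32 tested members rose and 2 fell (16 and 2 adjusted over the list alone). The cyclin Ccne1 stood at 87.9 ± 4.74 against 32 ± 1.84 FPKM (1.43). Camera called the replication list higher (median 0.27, adjusted p = 0.044, and adjusted p = 0.248 with an estimated correlation). The call was lost under upper quartile (adjusted p = 0.0754) and median of ratios (0.151) scaling, without trend (0.0518), and without KO_let-7g replicate 0 (0.0593) or KO_siNr6a1 replicate 2 (0.0698). Of the osteoblast and cartilage genes, 1 of 17 tested members rose and 4 fell (the same counts adjusted over the list alone). The homeobox gene Dlx5 stood at 3.33 ± 0.956 against 13.2 ± 3.13 (-1.72). Camera called the osteoblast and cartilage list lower (median -0.08, adjusted p = 0.0448, and adjusted p = 0.639 with an estimated correlation). That call was lost at a mean FPKM of at least 5 (0.327), under upper quartile (0.0754), quantile (0.0645) and median of ratios (0.151) scaling, without trend (0.0518), with library weights (0.0758) and without AGCCTT genes (0.0513). Without KO_let-7g replicate 0 (0.0593), KO_let-7g replicate 2 (0.0542) or KO_siNr6a1 replicate 1 (0.0966) it was lost as well. The other 15 lists were not called, but inflammation (5 and 9 of 22, adjusted p = 0.0534) was called lower with the replicate block (adjusted p = 0.0173). Among these lists median, mean and camera direction differed in sign for the fetal growth, Hox, p53, TGF-beta or YAP, stem cell and adipocyte lists. In all, 4826 genes passed the test, 3262 higher and 1564 lower in KO_let-7g, so that 67.6% were higher, against 51.9% under quantile scaling (2234 and 2070) and 48.5% under median of ratios scaling (2129 and 2260). The median log2 fold change of all genes in this comparison was 0.12 as deposited, 0.02 under quantile scaling and 0.00 under median of ratios scaling. Log2 fold changes in this comparison also went with transcript length (Spearman rho across 11200 genes -0.149, and -0.177, 0.034 and -0.269 by replicate number). In KO_let-7g against KO_siCtrl rho was -0.1, in KO_siNr6a1 against KO_siCtrl 0.04 and in KO_siCtrl against WT_siCtrl 0.067.

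Some genes moved the same way in both treatments. Arg2 fell in KO_let-7g and KO_siNr6a1 (-2.4 and -2.12), as did Sema7a (-2.1 and -2.36) and the keratin gene Krt13 (-1.96 and -1.89), and the glutathione transferase Mgst1 rose (1.9 and 1.87). In all, 1092 genes were called higher and 849 lower in both, 1941 together, where independent lists would share 775. Unchanged groups simulated against the same controls shared 0.01 on average. Such groups give almost no calls by construction, so this count cannot show how many shared calls the common controls add. Over all genes the signs were the same in 66%, against 67.1% simulated. A further 252 genes were called in opposite directions. The log2 fold changes had r = 0.53 across genes, which are not independent replicates, against 0.52 simulated, and a covariance of 0.138 against 0.0298 simulated, a difference of 0.108. The 3 KO_siCtrl libraries cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls. The count was 2973 with the replicate block and 1148 without replicate 0 of every group.

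Other genes that differed between KO_siCtrl and WT_siCtrl were moved back by a treatment. Arg2, Arid3a, Hmga2 and Kbtbd11 rose in KO_siCtrl (4.35, 2.69, 3.75 and 2.25) and fell in KO_let-7g. Itgb7 (3.97), Celf4 (1.77) and the apolipoprotein gene Apoc2 (1.85) rose in KO_siCtrl and fell in KO_siNr6a1, Apoc2 with a log2 fold change of -1.75, while Ephb6 fell (-2.33) and rose in KO_siNr6a1. The levels of Celf4, Apoc2 and Ephb6 also moved this way in KO_let-7g. Against KO_siCtrl, Celf4 stood at 8.17 ± 1.58 against 21.8 ± 2.41 FPKM, Apoc2 at 0 against 2.72 ± 0.34 and Ephb6 at 6.08 ± 1.64 against 2.86 ± 0.782. Of the 6413 genes called in KO_siCtrl against WT_siCtrl, let-7g moved back 2572 (40.1%), 1208 of them higher and 1364 lower in KO_siCtrl. It moved 696 further the other way. Independent lists would give 1441 moved back. The simulation gave 0.03, but unchanged groups give almost no calls by construction, so this sets no expected count. Over all genes the signs were opposite in 63.3%, against 69.8% simulated. Across genes the covariance was -0.191 against -0.0309 simulated, a difference of -0.16, and r was -0.41 against -0.53. The siRNA against Nr6a1 moved back 1617 (25.2%), 941 of them higher and 676 lower in KO_siCtrl, and it moved 555 the other way. Independent lists would give 951 moved back, and the simulation gave 0.02, with the same limit. Opposite signs were found in 61.2% of all genes, against 66.2% simulated. For the siRNA the covariance was -0.127 against -0.0285, a difference of -0.0986, and r was -0.33 against -0.47. Which direction held more of the genes moved back depended on scaling: 1366 were higher and 1156 lower for let-7g by quantiles, and 685 and 831 for the siRNA by median of ratios. The count for the siRNA was 2632 with the replicate block and 934 without replicate 0 of every group, and part of either excess may come from the shared KO_siCtrl libraries. Both treatments also replaced the control siRNA, so a gene moved back need not answer to let-7g or to Nr6a1.

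In a scan of 3′ UTR words, words overlapping AGCCTT went with higher expression in both treatments. The z values and their limits treat genes as independent, which they are not, and do not measure the spread between libraries. The word AAGCCTT had z = 12.95 in KO_let-7g against KO_siCtrl, beyond the permuted limit of 4.44, and 17.09 in KO_siNr6a1 against KO_siCtrl, beyond 4.58. Between the treatments its z was -0.03, and in KO_siCtrl against WT_siCtrl it was -4.11, inside the limit of -4.62. AGAGATA, which does not hold AGCCTT, also lay beyond both limits (5.58 and 7.675). The let-7 7mer CTACCTC had z = -19.55 in KO_let-7g, 0.69 in KO_siNr6a1, -23.05 between the treatments and 6.45 in KO_siCtrl against WT_siCtrl, beyond the limit of 4.54. AATATAA had z = -9.43 in KO_siNr6a1 against KO_siCtrl, beyond the limit of -4.46, and -0.53 in KO_let-7g against KO_siCtrl, with 7.62 between them. TATTTAT was low in both treatments, at -8.12 in KO_let-7g, beyond -4.49, and -6.49 in KO_siNr6a1, beyond -4.46. In KO_siCtrl against WT_siCtrl its z was 4.32, inside the limit of 4.54. Of the genes called higher in both treatments and with a 3′ UTR, 774 of 1068 (72.5%) held AGCCTT, against 43.7% of all such genes tested, a share not corrected for UTR length. Median log2 fold changes with and without AGCCTT were 0.14 and 0.03 in KO_let-7g and 0.03 and -0.11 in KO_siNr6a1.

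**Figure D4:**
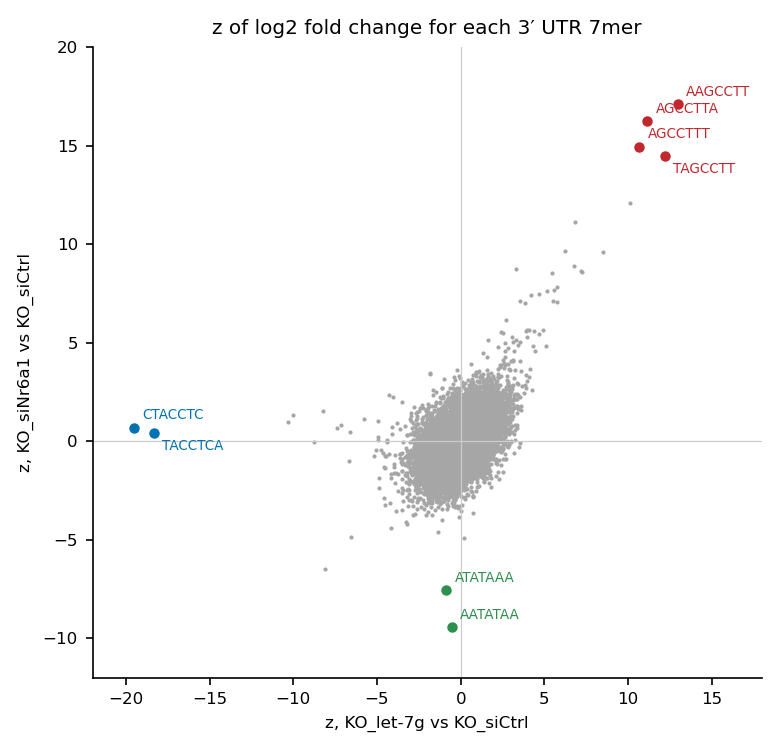
Each point is a 7-base word of the 3′ UTR, placed by its z for log2 fold change in KO_let-7g against KO_siCtrl (horizontal axis) and in KO_siNr6a1 against KO_siCtrl (vertical axis). AAGCCTT is high on both axes (12.95 and 17.09), CTACCTC is low on the horizontal axis alone (-19.55 and 0.69), and AATATAA is low on the vertical axis alone (-9.43, with -0.53 on the horizontal axis).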

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

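The tests without AGCCTT genes, without small RNA and predicted genes and without replicate 0 of every group were chosen only after the results were seen. The planned choice of the highest entry per gene name could not be run, as no name was duplicated. Total reads are not known, so precision at low FPKM rests on the spread between libraries. Of the named genes, 6043 values under settings that kept all libraries or dropped replicate 0 stayed on their side of the threshold, 136 lost the call and 1 gained it. With 1 library left out 4973 stayed and 187 lost it. For the called lists the counts were 323 and 22, and with 1 library left out 262 and 14. The causes of these changes were not tested unless stated.

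Nr6a1 between KO_let-7g and KO_siNr6a1, 0.14 and not called, turned to -0.029 under quantile scaling and to -0.011 without KO_let-7g replicate 1. Stricter thresholds leave fewer genes by construction: at least 1 log2 unit left 1459, 763, 310 and 499 genes in KO_siCtrl against WT_siCtrl, KO_let-7g against KO_siCtrl, KO_siNr6a1 against KO_siCtrl and KO_let-7g against KO_siNr6a1, and an adjusted p of 0.01 left 1887 and 3062 in the last 2. Camera with an estimated correlation called 0 lists in each comparison (4, 1, 1 and 3 at an unadjusted p under 0.05), and fry called 15, 10, 3 and 11. At a mean FPKM of at least 5, 8 lists were called in KO_let-7g against KO_siCtrl. The let-7 8mer difference in KO_siCtrl against WT_siCtrl lost its unadjusted call with an estimated correlation (0.146, p = 0.105), without a filter (0.00875, p = 0.0884) and without WT_siCtrl replicate 2 (0.132, p = 0.056).

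With the replicate block, 7684 genes were called in KO_siCtrl against WT_siCtrl, 6878 in KO_let-7g against KO_siCtrl and 6461 in KO_let-7g against KO_siNr6a1. The reported fit, which has no block, called 6413, 5383 and 4826. In KO_siNr6a1 against KO_siCtrl the block gave 5248 genes, genes shared by both treatments were 2973 and those moved back by KO_siNr6a1 2632. The block ended the ERK list call there, no other list or named gene call, and added 3 list calls. Library weights gave 5528, 2930 and 2616. Without AGCCTT genes, fewer genes were tested: 3458, 2679, 1649 and 2598 were called in the 4 comparisons, 810 were shared, 1312 and 780 were moved back by let-7g and by the siRNA against Nr6a1, and 6 lists were called in KO_siNr6a1 against KO_siCtrl. Without replicate 0 of every group, with fewer libraries, KO_siNr6a1 against KO_siCtrl gave 2021 genes, 1148 were shared and 934 moved back by KO_siNr6a1.

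With 1 library left out, called genes ranged over 5713 to 6372, 4569 to 5682, 2539 to 3789 and 3849 to 5174 in the 4 comparisons in the order above. Called lists ranged over 8 to 10, 3 (without KO_siCtrl replicate 2) to 6, 2 to 5 (without KO_siNr6a1 replicate 2) and 5 to 9. The 8mer difference ranged over 0.115 to 0.167, -0.391 to -0.352, 0.000265 to 0.0373 and -0.38 to -0.347, and Nr6a1 over 2.525 to 2.674, -1.455 to -1.186, -1.537 to -1.388 and -0.011 to 0.258. Dicer1 in KO_siCtrl against WT_siCtrl ranged over -0.719 to -0.475. Shared genes ranged over 1483 to 2133, and those moved back over 2116 to 2703 for let-7g and 1181 to 1741 for the siRNA against Nr6a1.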

Other observations

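The tests of small RNA genes in replicate 0 and of both explanations for the contractile genes, and the fits without AGCCTT genes and without replicate 0, were chosen only after the results were seen. Single stress and p53 genes rose under let-7g although neither list was called. Trib3 and Atf3, genes of the endoplasmic reticulum and amino acid stress response, rose in KO_let-7g against KO_siCtrl (92.8 ± 18.3 against 18 ± 4.31 FPKM, log2 fold change 2.31, and 25 ± 3.89 against 8.19 ± 0.853, 1.49), as did the asparagine synthetase Asns (279 ± 20.4 against 126 ± 14.5, 1.15). Of the stress genes, 10 of 23 tested members rose and 2 fell (11 and 2 adjusted over the list alone), with adjusted p = 0.103 by camera. Trp53inp1, a p53 target, rose to 14.8 ± 1.26 from 2.51 ± 0.838 (2.2), and of the p53 targets 4 of 21 tested members rose and 2 fell (the same counts adjusted over the list alone), with adjusted p = 0.99. Adjusted p by limma was at most 6.75e-05 for these genes.

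Single Hox, imprinted and microRNA processing genes fell under let-7g without a call for their lists. The Hox genes Hoxa7 (4.26 ± 0.622 against 14.6 ± 2.04 FPKM, -1.56) and Hoxa9 (12.3 ± 1.51 against 27.1 ± 1.82, -1.08) fell, as did the imprinted gene Peg10 (29.2 ± 8.14 against 98.2 ± 7.1, -1.75). Tarbp2, a partner of Dicer, stood at 23.6 ± 2.09 against 60.7 ± 9.75 (-1.32) and the Argonaute gene Eif2c2 at 13.8 ± 4.04 against 36.8 ± 7.29 (-1.38). Other members rose, among them the microRNA processing genes Dis3l2 (4.01 ± 0.00341 against 2.1 ± 0.211) and Eif2c1 (9 ± 0.819 against 6.16 ± 0.644) and the imprinted gene Cdkn1c (3.62 ± 0.696 against 1.24 ± 0.151). Of the Hox genes, 4 of 20 tested members rose and 6 fell (5 and 7 adjusted over the list alone), with adjusted p = 0.193, and of the imprinted and fetal growth genes, 3 of 13 tested members rose and 3 fell (the same counts adjusted over the list alone), with adjusted p = 0.588. Of the microRNA processing genes, 3 of 19 tested members rose and 9 fell (3 and 11 adjusted over the list alone), with adjusted p = 0.0798, or 0.0422 with the replicate block. Adjusted p by limma was at most 0.00347 for the named genes that fell.

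Across all 11801 tested genes, the covariance of the log2 fold changes in both treatments was 0.138, above the highest of 100 simulated for unchanged groups (0.0539). This argues against chance values of the shared controls as the whole cause of the joint changes. It is not particular to the 1092 genes called higher in both. Over all tested genes r was 0.53 against 0.52 simulated, and signs were the same in 66% against 67.1%. In the mean of both comparisons the word AAGCCTT had z = 16.75, beyond the permuted limit of 4.58. It was already the strongest word for higher genes in each of them, so this z adds no separate support. The word was found in these same fold changes, by a scan added after the data were examined. Such a word would be seen if the control siRNA lowered genes that hold its seed match. That is a candidate explanation only, since the sequence of that siRNA is not given in the sources used here. The lower Nr6a1 in both treatments stays open. The 1092 genes had a median log2 fold change of -0.267 in KO_siCtrl against WT_siCtrl. Simulation with the shared controls gave -0.109 on average and -0.268 at the lowest. The simulated genes were the 1092 with the largest smaller rise in unchanged groups, so noise alone picked them. The observed genes were picked by adjusted p in groups that differ, so these medians are not matched and cannot decide the question. Among the 294 of the 1092 observed genes without AGCCTT the median was -0.327. Of the 1092 genes, 48.4% were called lower in KO_siCtrl against WT_siCtrl, against 25.2% of all tested genes. These 294 genes and these shares were not simulated, and they rest on the same KO_siCtrl libraries.

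Libraries of the same number deviated from their group means together. Small RNA and predicted genes were 2.87% of tested genes and 43.0% to 74.5% of those that deviated by over 1 log2 unit in replicate 0, but among the other genes the replicate 0 deviations still correlated between groups (r = 0.48 to 0.684), which argues against those genes as the whole cause. The deviations of replicates 1 (0.231 to 0.383) and 2 (0.101 to 0.579) correlated as well. The replicate 0 deviation went with transcript length in each group (Spearman rho across 11200 genes 0.46, 0.337, 0.486 and 0.492), which may reflect a difference in library preparation or RNA fragmentation. No biological explanation was tested, as the labels do not say what the number stands for.

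For the contractile genes lower in KO_siCtrl, loss of let-7 alone and a difference between clonal lines stay open. Over the whole list let-7g moved back -0.048 of the fall (95% bootstrap interval over members -1.622 to 0.272). A second test, chosen after the first was seen, used the 10 members lower in KO_siCtrl and gave -0.01 (-0.084 to 0.074). Its interval covers only the spread between these members, which were picked by their fall in KO_siCtrl libraries that both comparisons share. It cannot exclude loss of let-7, as 48 h of let-7g need not undo a long loss. The list's median log2 fold change in KO_siCtrl against WT_siCtrl was -1.806, and a difference between clonal lines could give it as well as Dicer1, because genotype and line cannot be told apart here.

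With 3 against 3 libraries there are 10 splits, so a share under 0.05 cannot be reached. The real split gave 6413 genes in KO_siCtrl against WT_siCtrl, 5383 in KO_let-7g against KO_siCtrl, 3474 in KO_siNr6a1 against KO_siCtrl and 4826 between the treatments, and in each comparison 1 of the 10 splits, the real one, gave as many. The highest of the other splits gave 2 genes in each comparison. Each of those splits mixes the 2 groups, so the difference between the groups counts as spread and almost no calls follow by construction. These low counts are therefore no evidence against chance. The real split parts all 3 same-number pairs, and the 3 other splits that also part all of them gave 0 to 2 genes, while the rest keep 2 of the pairs together.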
